A study of Mus musculus with 30 samples.

How the data were processed

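Messenger RNA was sequenced, per the labels, from C57BL/6 bone marrow derived macrophages grown with CSF-1 at 20 ng/mL to day 7, with stranded poly(A) libraries on a HiSeq instrument. The labels give IL-4 at 20 ng/mL, PGE2 at 10 µM and valinomycin at 10 nM, and no stimulation time. They name 1 control and 1 Etv1 hairpin group and do not give the hairpin sequences. The deposited values were raw read counts per Ensembl gene, 1 table for each of 30 libraries with 43629 gene IDs, and the authors made them, per the submitters' processing notes, with STAR, featureCounts and the GRCm38 mouse genome, without stated versions. The notes also name DESeq2 and deepTools, whose output was not used here. The strand setting of the counting was not given in the sources used here, so counts of overlapping and antisense genes, such as Dnmt3aos, are uncertain, as are those of genes with near-identical copies.

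Gene symbols and coordinates were taken from GENCODE M21 on GRCm38. Of the gene IDs, 42548 (97.52%) matched, and the unmatched IDs held 0.153% of reads. The wild type experiment had 12 libraries with 10514496 to 13414293 counts each and the shRNA experiment 18 libraries with 6924973 to 30473040 (median 10303938). A floor of 3 counts over a group was used for bounds, and 95% counting intervals for ratios over 1 to 3 counts were exact binomial. No library pair differed by as little as sampling noise: the lowest chi-square per degree of freedom among replicates was 1.246 (p = 2.19e-71), so each was counted as its own replicate. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

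Each experiment was fitted alone, with all its groups in a model that shared the estimate of spread. Counts were tested with edgeR 4.0.16 (robust quasi-likelihood fit, TMM normalization, filterByExpr) in R 4.3.3, which kept 12824 genes in wild type and 12382 in shRNA libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes came from that fit with the default prior count of edgeR. A prior count of 2 was used for the log2 CPM of the list and set tests and of the correlations between libraries, not for fold changes. The standard error (SE) of a log2 fold change was its absolute value over the square root of the F statistic. CPM used TMM effective library sizes within an experiment, given as mean ± SD over 3 libraries. Levels are therefore compared within an experiment, not between experiments. The contrasts were IL-4 against no stimulus, PGE2 or valinomycin on top of IL-4 against IL-4, PGE2 against valinomycin, Etv1 against control shRNA in each condition, and the differences of the PGE2 and IL-4 effects between hairpins. Where fold changes of a group at or near 0 counts depended on the prior count, a bound or a ratio of counts was given in their place.

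The comparisons, lists, named genes and first set of alternatives were fixed before the data were examined. There were 25 lists: alternative activation, cAMP targets, prostaglandin pathway, malate-aspartate shuttle, TCA cycle, nuclear OXPHOS, mtDNA-encoded genes, glycolysis, HIF targets, integrated stress response, cholesterol synthesis, fatty acid oxidation, lysosome, interferon response, inflammatory mediators, antigen presentation, cell cycle, ETS factors, macrophage identity, and markers of neutrophils, dendritic cells, lymphocytes, stromal cells, mast cells and basophils, and erythroid cells and megakaryocytes. Some genes sit on more than 1 list, such as Ptgs2, Vegfa, Klf4 and Mdh2. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists with at least 2 tested members in a contrast, and again with an estimated correlation and with fry. These were all 25 lists in wild type and 24 in the shRNA contrasts, where the mast cell and basophil list had 1 tested member and was not tested. Of 316 list tests, 92 passed with the preset correlation and 8 of these also with the estimated one: alternative activation in the 3 IL-4 contrasts, cell cycle in the IL-4 contrasts of both hairpins, inflammatory mediators for the hairpin under IL-4 with PGE2, and cAMP and HIF targets in the difference of the PGE2 effects. For each list the members called with adjustment over all genes were counted, and also those called when adjusted over the list alone, which is given where the counts differ and the list is discussed at length. The genes named were Etv1, Got1, Retnla, Arg1, Chil3, Crem and Ptgs2 always, the 8 raised and 8 lowered genes of each contrast with the largest log2 fold change, up to 4 members of each list with the smallest adjusted p, and the 8 raised and 8 lowered genes with the largest change shared by PGE2 and valinomycin. The largest changes were taken among called genes with at least 5 CPM in the higher group, fully separated groups and a symbol that is not a model name; the differences between hairpins needed 5 CPM in the highest of 4 groups and no separation. Genes named outside this rule are said to have been chosen after their values were seen.

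For calls shared by comparisons against the same IL-4 libraries, 20 simulations drew unchanged groups against those libraries, and the overlap of independent lists was computed per direction. Replicate numbers are shared by the groups in the labels' titles. Same-numbered libraries deviated together within each hairpin, with every correlation of the deviations from the group means over 0.1: 0.213 to 0.49 and 0.146 to 0.433 for IL-4 and PGE2 with control shRNA, and 0.187 to 0.325 and 0.106 to 0.293 with Etv1 shRNA, so the numbers were taken to pair those libraries. The 3 control shRNA libraries numbered 2 stood apart from the other control shRNA libraries.

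Alternatives were DESeq2 1.42.0, DESeq2 size factors inside edgeR, no filter, a filter of 5 CPM in at least 1 group, the replicate number as a block, a fit of only the compared groups, a fit of all 30 libraries, at least a 2-fold change for shared calls and sets, and leaving out each library. Leaving out the control shRNA libraries numbered 2 and a replicate block nested in the hairpin were chosen after seeing the data. Scaling by DESeq2 size factors moved the median of all genes by at most 0.0181 on the log2 scale. On simulated counts with 200 changed genes, edgeR recovered 71.6%, 91% and 97% of 1.5-fold, 2-fold and 4-fold changes for the wild type PGE2 comparison (12659 genes, 5.98% of calls false) and 38.8%, 70.1% and 84.8% for the difference of the PGE2 effects (12173 genes, 9.79% of calls false). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.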

Results

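The series measured messenger RNA in bone marrow derived macrophages of C57BL/6 mice, which were grown with 20 ng/mL CSF-1, the growth factor that turns bone marrow progenitors into macrophages, and used on day 7. There were 30 libraries in 10 groups of 3. Wild type cells were left unstimulated or given IL-4 at 20 ng/mL, IL-4 with prostaglandin E2 (PGE2) at 10 µM, or IL-4 with valinomycin at 10 nM. IL-4 drives alternative activation of macrophages, PGE2 raises cyclic AMP through its receptors, and valinomycin is a potassium ionophore that lowers the membrane potential of mitochondria. Cells transduced with a lentiviral control short hairpin RNA (shRNA) or an shRNA against Etv1, a transcription factor of the ETS family, were left unstimulated or given IL-4 or IL-4 with PGE2. Library totals ran from 10514496 to 13414293 counts in the wild type experiment and from 6924973 to 30473040 in the shRNA experiment. Within the latter, totals were 9981301 to 20658411 in unstimulated, 9209367 to 14159884 in IL-4 and 8990406 to 30473040 in IL-4 with PGE2 control shRNA libraries. In Etv1 shRNA libraries they were 6924973 to 11907864, 9286288 to 10344596 and 9555237 to 11587131. A floor of 3 counts corresponded to 0.22 to 0.29 CPM (counts scaled to library size) in wild type libraries and 0.098 to 0.43 CPM in shRNA libraries. Intervals and floors given here cover counting error only.

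Etv1 (ENSMUSG00000004151, chromosome 12, 38779380 to 38870484, GRCm38) was measured first, since it is the target of the hairpin. Its level was 3.44 ± 1.23, 5.33 ± 0.58 and 8.88 ± 1.08 CPM (mean ± SD, n = 3) in Etv1 shRNA cells that were unstimulated, given IL-4 and given IL-4 with PGE2. In control shRNA cells the same conditions gave 10.6 ± 0.289, 13.9 ± 2.07 and 28 ± 5.72 CPM. The hairpin contrast was -1.69 ± 0.20, -1.39 ± 0.19 and -1.67 ± 0.16 on the log2 scale (± SE), with edgeR adjusted p = 1.16e-06, 4.41e-06 and 5.4e-08, so the labels and the target went the same way in each condition. Wild type cells held 11.6 ± 0.58 CPM unstimulated, 13.5 ± 0.818 with IL-4, 29.8 ± 0.859 with IL-4 and PGE2 and 13.4 ± 1.58 with IL-4 and valinomycin. PGE2 raised Etv1 over IL-4 by 1.14 ± 0.09 in wild type (adjusted p = 1.04e-10), by 1.02 ± 0.15 in control shRNA (1.2e-05) and by 0.74 ± 0.20 in Etv1 shRNA cells (0.00383). With valinomycin the log2 difference was -0.01 ± 0.10 (adjusted p = 0.948), and PGE2 exceeded valinomycin by 1.15 ± 0.09 (6.88e-11). For IL-4 alone the differences were 0.23 ± 0.10 in wild type (adjusted p = 0.0706), 0.40 ± 0.17 in control shRNA (0.0711) and 0.70 ± 0.23 in Etv1 shRNA cells (0.0416). With the replicate number as a block, the control shRNA value was 0.391 with adjusted p = 0.0156. Leaving out control shRNA IL-4 replicate 2 gave 0.51 with adjusted p = 0.027. The Etv1 shRNA value ranged from 0.514 to 0.95 when 1 library was left out and kept its call only without unstimulated replicate 1.

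**Figure D1:**
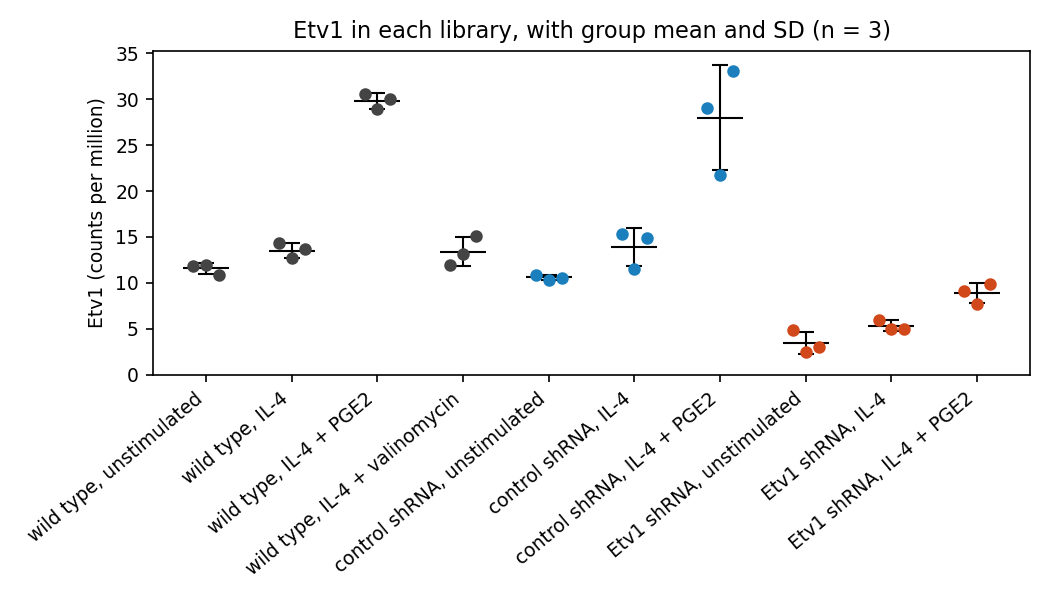
Etv1 level in CPM (linear axis) in each of the 30 libraries by group, with the group mean and SD (n = 3) as black bars. The mean was 28 CPM with control shRNA and 8.88 CPM with Etv1 shRNA under IL-4 and PGE2.

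IL-4 was compared with no stimulus in wild type cells to show what the cytokine does alone. It raised the hallmark genes of alternative activation. Arg1, which encodes arginase 1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), stood at 1080 ± 60.6 against 2.68 ± 0.368 CPM, a log2 change of 8.66 ± 0.10 (edgeR adjusted p = 5.24e-26, n = 3 per group). Retnla, a secreted resistin-like protein, had a single count over the unstimulated libraries and 55.7 ± 10.4 CPM with IL-4, a ratio of 1960-fold (95% counting interval 352 to 77500). The checkpoint ligand gene Pdcd1lg2 rose by 8.69 ± 0.20, the lectin gene Mgl2 by 6.78 ± 0.10, the signalling inhibitors Cish and Socs1 by 6.82 ± 0.14 and 6.79 ± 0.13, and Chil3 from 45.9 ± 2.32 to 247 ± 6.76 CPM. Msx3, a homeobox gene, had 3 counts unstimulated and a ratio of 755-fold (95% counting interval 258 to 3660). Of the alternative activation list, 27 of 28 measured members rose and 0 fell (camera adjusted p = 1.07e-31, and adjusted p = 0.000484 with an estimated correlation). The fractalkine receptor gene Cx3cr1 had the largest fall, -4.86 ± 0.13 (3.17 ± 0.431 against 92.1 ± 11.4 CPM), followed by Sncaip (-3.06), Nanos1 (-2.75), the sphingosine receptor gene S1pr1 (-2.73) and the Notch ligand gene Jag1 (-2.46).

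Other lists also moved with IL-4 in wild type. Of genes for nuclear-encoded subunits of oxidative phosphorylation (OXPHOS), 48 of 76 measured members rose and 0 fell, among them Uqcrc1 (0.55 ± 0.05) and Atp5b (0.34 ± 0.05). Adjusted over the list alone, 52 rose and 0 fell, and camera gave adjusted p = 2.75e-07, but adjusted p = 0.664 with an estimated correlation. Of tricarboxylic acid (TCA) cycle genes, 14 of 22 measured members rose and 0 fell, with Mdh2 at 0.39 ± 0.05 and Suclg1 at 0.35 ± 0.06. The TCA list had camera adjusted p = 0.00393, and adjusted p = 0.408 with an estimated correlation. Of cell cycle genes, 0 of 35 measured members rose and 28 fell, including Pcna (-0.59 ± 0.04) and Mcm6 (-0.57 ± 0.06), with camera adjusted p = 1.91e-07 and adjusted p = 0.317 with an estimated correlation. Of interferon response genes, 4 of 27 measured members rose and 21 fell, such as Oas3 at -1.11 ± 0.07 and Rtp4 at -1.21 ± 0.09. The interferon list had camera adjusted p = 0.000265, and adjusted p = 0.317 with an estimated correlation. Antigen presentation genes rose as a list (8 rose and 0 fell of 12), with H2-DMa at 1.47 ± 0.07 and the class II transactivator Ciita at 2.29 ± 0.20. The antigen presentation list had camera adjusted p = 0.00393, and adjusted p = 0.0991 with an estimated correlation. Of dendritic cell markers 4 rose and 0 fell of 5, with Zbtb46 at 3.19 ± 0.35. The dendritic list had camera adjusted p = 0.0174, and adjusted p = 0.173 with an estimated correlation. Among 12824 genes tested, 5952 changed (3084 higher, 2868 lower), of which 561 rose and 378 fell at least 2-fold.

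PGE2 on top of IL-4 was the main comparison of the study, which asked how nuclear gene expression follows mitochondrial membrane potential under PGE2. Thbs1, the gene of the secreted matrix protein thrombospondin 1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), rose most, from 13 ± 0.502 to 4030 ± 308 CPM (log2 8.27 ± 0.19, edgeR adjusted p = 1.13e-10, n = 3 per group). The flagellin receptor gene Tlr5 (7.60 ± 0.15; 70.6 ± 3.67 against 0.355 ± 0.0694 CPM), the receptor phosphatase gene Ptprf (7.03 ± 0.22), the receptor accessory gene Ramp3 (7.02 ± 0.23), the chromatin organiser Satb1 (5.97 ± 0.18) and Trem1 (5.76 ± 0.20) followed. The uracil glycosylase gene Ung (-4.28 ± 0.27), Chn2 (-3.61 ± 0.13), the transcription factor Batf3 (-3.58 ± 0.12; 2.85 ± 0.333 against 34.3 ± 2.96 CPM), the cholesterol hydroxylase Ch25h (-3.26 ± 0.33) and Retnla (-3.26 ± 0.20; 5.71 ± 1.46 against 55.7 ± 10.4 CPM) had the largest falls. Got1, the cytosolic aspartate aminotransferase of the malate-aspartate shuttle (ENSMUSG00000025190, chromosome 19, 43499752 to 43524605), rose from 45.8 ± 2.72 to 119 ± 6.01 CPM (1.38 ± 0.06, adjusted p = 3.9e-15). In all, 7617 of 12824 genes changed (3837 higher, 3780 lower), 679 of them at least 2-fold higher and 601 at least 2-fold lower.

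Of the cyclic AMP target list, 18 of 24 measured members rose and 2 fell with PGE2 in wild type. Crem, whose inducible repressor forms answer to cyclic AMP, went from 11.9 ± 1.31 to 311 ± 18.5 CPM (4.70 ± 0.08), the phosphodiesterase genes Pde3b and Pde4b rose by 3.38 ± 0.07 and 3.19 ± 0.08, and Atf3 fell (-1.98 ± 0.05). Camera gave adjusted p = 1.34e-06 for that list, and adjusted p = 0.273 with an estimated correlation. The alternative activation list split: 11 rose and 11 fell of 28 measured members (adjusted over the list alone, 12 rose and 12 fell; camera adjusted p = 0.958). Arg1 rose further, from 1080 ± 60.6 to 4530 ± 203 CPM (2.07 ± 0.06), as did the transglutaminase gene Tgm2 (3.11 ± 0.06), Mgl2 (1.69 ± 0.05) and Il4ra (1.77 ± 0.05), while Retnla and Batf3 fell and Chil3 stood at 247 ± 6.76 and 269 ± 13.1 CPM. Of targets of hypoxia inducible factor (HIF), 11 rose and 2 fell of 18, with Mxi1 at 1.93 ± 0.18. The HIF list had camera adjusted p = 0.0234, and adjusted p = 0.864 with an estimated correlation. Of ETS family genes, 9 rose and 2 fell of 16, led by Ets2 (2.52 ± 0.06; 361 ± 12.1 against 63.2 ± 5.27 CPM) and Elk3 (1.08 ± 0.06; list camera adjusted p = 0.0234, and adjusted p = 0.273 with an estimated correlation). The platelet chemokine genes Ppbp (2.82 ± 0.18) and Pf4 (1.37 ± 0.06), which macrophages also express, were the risen members of the erythroid and megakaryocyte markers (2 rose and 0 fell of 3; camera adjusted p = 0.037, and adjusted p = 0.273 with an estimated correlation).

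Many genes of the nuclear OXPHOS, TCA cycle and cell cycle lists fell with PGE2. Of nuclear OXPHOS genes, 2 of 76 measured members rose and 47 fell, with Atp5b at -0.46 ± 0.05 and Ndufs7 at -0.55 ± 0.06. The OXPHOS list had camera adjusted p = 4.92e-05, and adjusted p = 0.846 with an estimated correlation. Of TCA cycle genes, 0 rose and 14 fell of 22 (adjusted over the list alone, 0 rose and 15 fell), with Idh2 at -0.92 ± 0.06 and Idh3a at -0.81 ± 0.07. The TCA cycle list had camera adjusted p = 0.00073, and adjusted p = 0.303 with an estimated correlation. Of cell cycle genes, 1 rose and 31 fell of 35, including the replication genes Mcm6 (-2.27 ± 0.07), Mcm7 (-1.39 ± 0.07) and Pcna (-1.20 ± 0.05), with camera adjusted p = 1.31e-10 and adjusted p = 0.273 with an estimated correlation. In the malate-aspartate shuttle 1 rose and 4 fell of 7: Got1 rose, while Slc25a13, a mitochondrial aspartate and glutamate carrier, fell by 1.79 and Got2 fell by 0.25 (list camera adjusted p = 0.487).

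The remaining lists did not pass camera for PGE2 in wild type. Members rose and fell, respectively, in these numbers: prostaglandin pathway 4 and 7 of 14 (adjusted p = 0.372), glycolysis 10 and 5 of 23 (0.416), fatty acid oxidation 2 and 12 of 19 (0.0511), lysosome 4 and 10 of 25 (0.245), and integrated stress response 5 and 9 of 26 (0.245). For cholesterol synthesis they were 7 and 1 of 23 (0.27), for interferon response 10 and 4 of 27 (0.0812), for inflammatory mediators 8 and 6 of 19 (0.809), for antigen presentation 3 and 4 of 12 (0.809), and for genes encoded by mitochondrial DNA (mtDNA) 3 and 0 of 8 (0.238). Cell type markers gave 5 and 4 of 16 for macrophage identity (0.502), 1 and 0 of 11 for neutrophils (0.816), 2 and 3 of 5 for dendritic cells (0.502), 0 and 0 of 3 for lymphocytes (0.946), 1 and 0 of 3 for stromal cells (0.74) and 0 and 1 of 2 for mast cells and basophils (0.502). Single members moved strongly within them: the costimulatory genes Cd86 (4.08 ± 0.09) and Cd80 (2.77 ± 0.10) rose while H2-DMa fell (-1.21 ± 0.07), and the amino acid transporter gene Slc7a5 (-2.32 ± 0.19) and the serine enzyme genes Shmt2 (-1.36 ± 0.09) and Phgdh (-1.40 ± 0.15) fell.

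**Figure D2:**
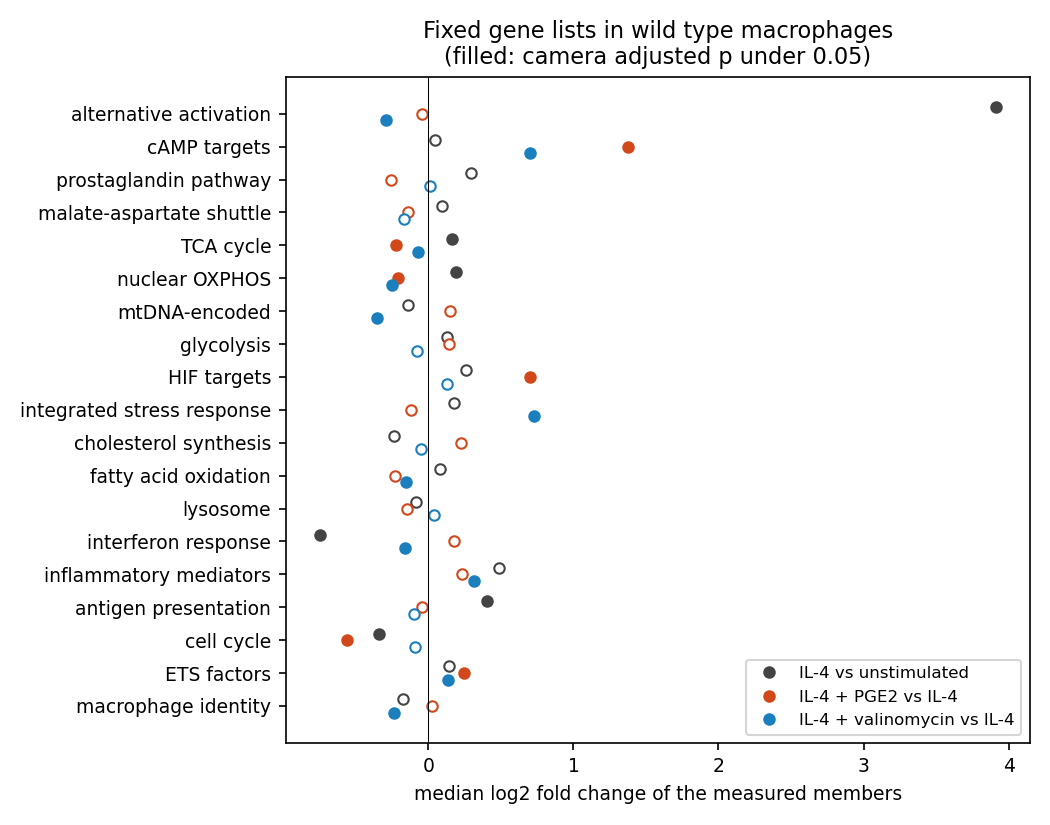
Median log2 fold change of the measured members of 19 fixed gene lists in 3 wild type comparisons (n = 3 libraries per group); filled points had a camera adjusted p under 0.05 with the preset correlation, open points did not. Alternative activation lay at 3.91 with IL-4, and nuclear OXPHOS genes lay below 0 with PGE2 and with valinomycin.

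Valinomycin on top of IL-4 was compared with IL-4 alone in wild type cells. Membrane potential was not analysed here, so the changes are those of the treatment as a whole. Chac1, a glutathione-degrading enzyme induced by the integrated stress response, rose most, from 0.783 to 29.1 CPM (5.19 ± 0.21, edgeR adjusted p = 5.53e-14, n = 3 per group). The mitochondrial ribosomal RNAs mt-Rnr2 (4.96 ± 0.23; 5350 ± 407 against 173 ± 54.2 CPM) and mt-Rnr1 (4.80 ± 0.11; 2660 ± 88.7 against 95.4 ± 16.1 CPM) came next. The stress cytokine gene Gdf15 (3.32 ± 0.21; 108 ± 26.7 against 10.8 ± 1.73 CPM), Trib3 (3.27 ± 0.21), Rasd2 (3.54 ± 0.23) and the chemokine gene Cxcl2 (3.09 ± 0.21) also rose. Falls were smaller: the tubulin gene Tuba8 (-1.77 ± 0.19), the activity-regulated genes Arc (-1.70 ± 0.16) and Npas4 (-1.48 ± 0.12), B3gnt7 (-1.38 ± 0.13) and the polyamine enzyme Amd1 (-1.25 ± 0.10). Got1 rose by 0.50 ± 0.06 (adjusted p = 1.36e-06), Retnla fell by 1.10 and Arg1 was at 1080 ± 60.6 and 820 ± 70.1 CPM (-0.40 ± 0.06, adjusted p = 6.89e-06). Of 12824 genes, 4919 changed (2491 higher, 2428 lower), 194 of them at least 2-fold higher and 53 at least 2-fold lower.

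**Figure D3:**
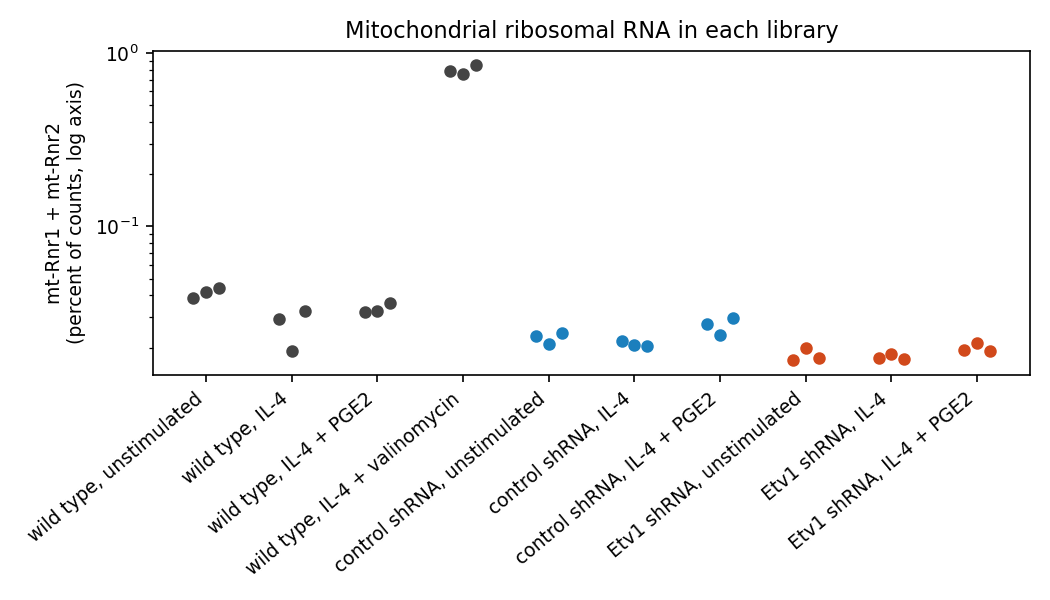
Share of counts on mt-Rnr1 and mt-Rnr2 in percent (log axis) in each of the 30 libraries by group, 1 point per library. The 3 valinomycin libraries lay between 0.751 and 0.846% and the other 27 libraries between 0.017 and 0.0444%.

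Of the integrated stress response list, 17 of 26 measured members rose and 1 fell with valinomycin (adjusted over the list alone, 18 rose and 1 fell). They included the transcription factors Atf4 (1.57 ± 0.06) and Ddit3 (2.52 ± 0.10) and the mitochondrial folate enzyme Mthfd2 (1.68 ± 0.09). Camera gave adjusted p = 1.49e-13, and adjusted p = 0.335 with an estimated correlation. Of nuclear OXPHOS genes, 0 rose and 52 fell of 76, with small changes such as Uqcr11 at -0.55 ± 0.07 (adjusted over the list alone, 0 rose and 58 fell). The OXPHOS list there had camera adjusted p = 1.49e-13, and adjusted p = 0.335 with an estimated correlation. Of mtDNA-encoded protein genes, 0 rose and 4 fell of 8, with mt-Cytb at -0.58 ± 0.10 and mt-Nd4 at -0.42 ± 0.08. The mtDNA list had camera adjusted p = 0.0326, and adjusted p = 0.57 with an estimated correlation. TCA cycle genes fell as a list (1 rose and 9 fell of 22; camera adjusted p = 0.0326, and adjusted p = 0.467 with an estimated correlation). Fatty acid oxidation genes did likewise (2 rose and 9 fell of 19; camera adjusted p = 0.0234, and adjusted p = 0.335 with an estimated correlation). Of cyclic AMP targets, 13 rose and 2 fell of 24, with Sik1 at 1.68 ± 0.08, Per1 at 1.24 ± 0.06 and Rgs1 at 1.19 ± 0.06, whereas Crem was at 11.9 ± 1.31 and 14.1 ± 2.18 CPM. The cyclic AMP list had camera adjusted p = 1.64e-06, and adjusted p = 0.335 with an estimated correlation. Inflammatory mediators rose as a list (7 rose and 1 fell of 19; Nfkbia 1.54 ± 0.10, Tnf 1.02 ± 0.10; camera adjusted p = 0.0234, and adjusted p = 0.467 with an estimated correlation). So did ETS factors (7 rose and 2 fell of 16; Etv3 0.74 ± 0.05, Ets2 0.63 ± 0.06; camera adjusted p = 0.0408, and adjusted p = 0.335 with an estimated correlation). Alternative activation genes fell (4 rose and 17 fell of 28; Socs1 -0.88 ± 0.07, Fn1 -0.76 ± 0.06, against a rise of Pparg, 0.72 ± 0.06; camera adjusted p = 0.0127, and adjusted p = 0.335 with an estimated correlation).

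PGE2 and valinomycin were then compared with each other, since both were given on top of IL-4 in the same experiment. Genes that moved with both included the lectin receptor gene Clec4e (PGE2 4.20 ± 0.25, valinomycin 2.34 ± 0.30), Cxcl2 (1.75 ± 0.25 and 3.09 ± 0.21) and the cytokine gene Osm (1.68 ± 0.11 and 1.83 ± 0.11). Further ones were Socs3 (2.05 ± 0.17 and 1.58 ± 0.18), Rab20 (1.56 ± 0.14 and 1.94 ± 0.14), Thbs1 (8.27 and 1.65 ± 0.19) and Spsb1 (2.63 ± 0.14 and 1.41 ± 0.16). Npas4 (-2.29 ± 0.14 and -1.48 ± 0.12), Tuba8 (-1.53 ± 0.18 and -1.77 ± 0.19), Angptl4 (-1.56 ± 0.15 and -1.16 ± 0.14), Klf2 (-1.32 ± 0.13 and -1.01 ± 0.13) and Retnla fell with both. In all, 2058 genes were called in the same direction, 1024 higher and 1034 lower, where independent lists would share 745.3 and 715.7. A further 1237 were called in opposite directions, where independent lists would share 1460.7. The correlation of the fold changes across genes, which are not independent replicates, was 0.168 (Spearman 0.181). Simulated unchanged groups against the same IL-4 libraries gave a correlation of 0.495 (0.479 to 0.512 over 20 simulations) and 0.2 shared calls, because noise of the shared libraries then makes up the fold changes. The covariance was 0.0478 against 0.012 in the simulations (0.0113 to 0.0129), a difference of 0.0358. The 3 IL-4 libraries were not split, since a part would hold a single library, so part of the excess may come from the shared controls. The PGE2 effect in control shRNA cells shares no library with the valinomycin effect, and there 1974 genes went the same way (1021 higher and 953 lower, against 725.6 and 736.2 for independent lists) and 1170 the opposite way, with r = 0.144 and a covariance of 0.0492 across 11906 genes.

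**Figure D4:**
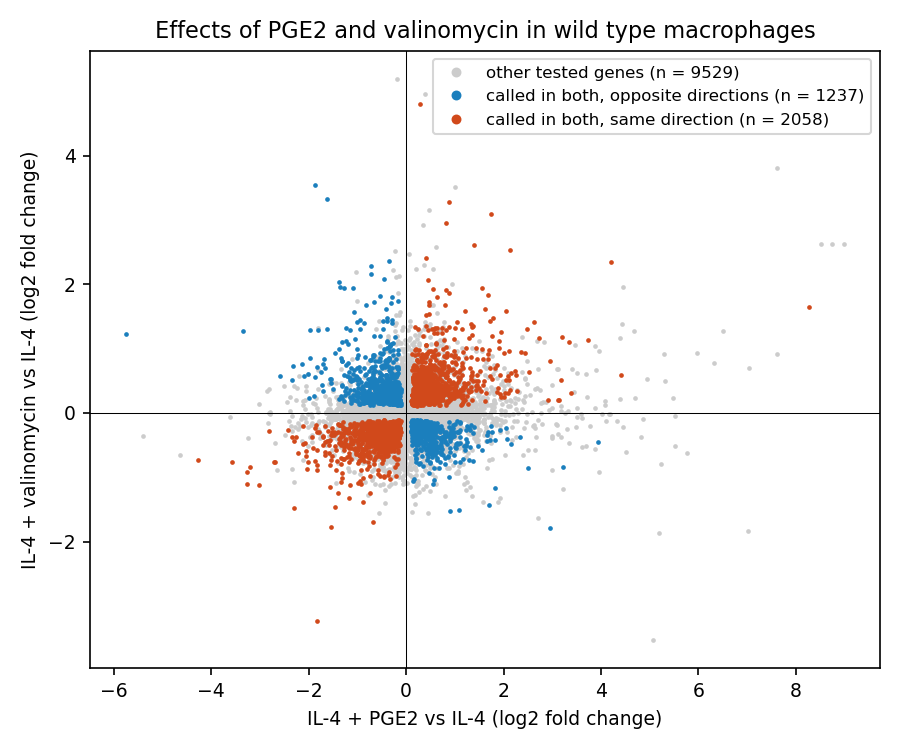
Log2 fold change with valinomycin against log2 fold change with PGE2, both relative to the same 3 IL-4 libraries, 1 point per gene (12824 genes). Of the genes called in both, 2058 went the same way and 1237 the opposite way.

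Tested directly against valinomycin, PGE2 left the integrated stress response genes lower: 1 rose and 19 fell of 26, with Chac1 at -5.39 ± 0.22, Gdf15 at -4.94 ± 0.26, Asns at -2.20 ± 0.08 and Atf4 at -1.69 ± 0.06. The stress response list had camera adjusted p = 6.76e-08, and adjusted p = 0.418 with an estimated correlation. Cell cycle genes were also lower with PGE2 (0 rose and 30 fell of 35; camera adjusted p = 1.16e-09, and adjusted p = 0.418 with an estimated correlation). The mtDNA-encoded genes were higher (6 rose and 0 fell of 8; camera adjusted p = 0.0155, and adjusted p = 0.611 with an estimated correlation). Higher with PGE2 were also cyclic AMP targets (15 rose and 6 fell of 24; camera adjusted p = 0.0155, and adjusted p = 0.611 with an estimated correlation) and HIF targets (12 rose and 3 fell of 18; camera adjusted p = 0.0382, and adjusted p = 0.713 with an estimated correlation). So were interferon genes (14 rose and 2 fell of 27; camera adjusted p = 0.0101, and adjusted p = 0.611 with an estimated correlation) and macrophage identity genes (11 rose and 3 fell of 16; camera adjusted p = 0.0278, and adjusted p = 0.611 with an estimated correlation). A further list was erythroid and megakaryocyte markers (3 rose and 0 fell of 3; camera adjusted p = 0.0298, and adjusted p = 0.418 with an estimated correlation). Tlr5 (6.70 ± 0.13), Thbs1 (6.62 ± 0.17), Trem1 (6.38 ± 0.22) and the collagen-binding integrin gene Itga1 (5.19 ± 0.16) were higher with PGE2. Ramp3 had 2 counts with valinomycin and a ratio of 544-fold (95% counting interval 150 to 4500). Got1 was higher by 0.88 ± 0.06 and Crem by 4.47 ± 0.08. In all, 8099 genes differed by edgeR (4062 higher with PGE2, 4037 lower), 778 of them at least 2-fold higher and 720 at least 2-fold lower.

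The IL-4 effect was measured again in transduced cells. In control shRNA cells Arg1 went from 0.307 ± 0.0952 to 596 ± 89.9 CPM (10.78 ± 0.38, edgeR adjusted p = 8.06e-11, n = 3 per group), and in Etv1 shRNA cells from 1.77 ± 0.9 to 224 ± 51.2 CPM (6.91 ± 0.32, 4.68e-09). Retnla was at 0 counts in unstimulated control shRNA cells and at least 74.8-fold higher with IL-4, where the floor was 3 counts over the group, and in Etv1 shRNA cells its ratio was 2340-fold (95% counting interval 420 to 92500) over a single count. The IL-31 receptor gene Il31ra was at least 131-fold higher in control shRNA cells and the aquaporin gene Aqp3 at least 101-fold higher in Etv1 shRNA cells. The transcription factor Irf4 rose under both hairpins (6.77 ± 0.27 and 5.20 ± 0.27). The alternative activation list rose under both hairpins. With control shRNA 27 rose and 0 fell of 28 (camera adjusted p = 6.69e-26, and adjusted p = 0.00369 with an estimated correlation). In Etv1 shRNA cells 23 rose and 0 fell of 28 (camera adjusted p = 5.86e-29, and adjusted p = 0.00228 with an estimated correlation). Cell cycle genes fell under both. With control shRNA 0 rose and 32 fell of 35, such as Top2a (-1.18 ± 0.06; camera adjusted p = 4.63e-20, and adjusted p = 0.00362 with an estimated correlation). Under the Etv1 hairpin 0 rose and 31 fell of 35, such as Mcm5 (-0.79 ± 0.09; camera adjusted p = 4.18e-24, and adjusted p = 0.00155 with an estimated correlation). Other lists passed too. Antigen presentation genes rose as a list with control shRNA (6 rose and 0 fell of 12; camera adjusted p = 0.0011, and adjusted p = 0.238 with an estimated correlation) and Etv1 shRNA (5 rose and 0 fell of 12; camera adjusted p = 0.000719, and adjusted p = 0.212 with an estimated correlation). Nuclear OXPHOS genes rose as a list with control shRNA (15 rose and 1 fell of 76; adjusted over the list alone, 8 rose and 0 fell; camera adjusted p = 0.0159, and adjusted p = 0.831 with an estimated correlation) and Etv1 shRNA (8 rose and 0 fell of 76; adjusted over the list alone, 2 rose and 0 fell; camera adjusted p = 0.0429, and adjusted p = 0.704 with an estimated correlation). Fatty acid oxidation genes rose as a list with control shRNA (8 rose and 0 fell of 19; camera adjusted p = 0.0159, and adjusted p = 0.387 with an estimated correlation) and Etv1 shRNA (4 rose and 0 fell of 19; camera adjusted p = 0.0272, and adjusted p = 0.385 with an estimated correlation). Cholesterol synthesis genes fell as a list with control shRNA (0 rose and 11 fell of 23; camera adjusted p = 0.0137, and adjusted p = 0.57 with an estimated correlation) and Etv1 shRNA (0 rose and 5 fell of 23; camera adjusted p = 0.0203, and adjusted p = 0.581 with an estimated correlation). Glycolysis genes fell as a list with control shRNA (3 rose and 14 fell of 23; camera adjusted p = 0.00384, and adjusted p = 0.396 with an estimated correlation). With Etv1 shRNA, TCA cycle genes (5 rose and 0 fell of 22; camera adjusted p = 0.0203, and adjusted p = 0.261 with an estimated correlation) and prostaglandin pathway genes (5 rose and 1 fell of 14; camera adjusted p = 0.0429, and adjusted p = 0.17 with an estimated correlation) rose as lists. Cx3cr1 fell with control shRNA (-3.96 ± 0.20) and with Etv1 shRNA (-1.51 ± 0.30), and Cd14 likewise (-2.49 ± 0.26 and -1.63 ± 0.26). IL-4 changed 4247 of 12382 genes in control shRNA cells (2130 higher, 2117 lower) and 2233 in Etv1 shRNA cells (1346 higher, 887 lower), 1865 of them in the same direction under both. With wild type, the control shRNA calls shared 3045 genes in the same direction and 73 in the opposite one.

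PGE2 acted in transduced cells on many of the genes it moved in wild type. Thbs1 went from 5.94 ± 3.75 to 9440 ± 3020 CPM with control shRNA (10.69 ± 0.49, edgeR adjusted p = 7.43e-10, n = 3 per group) and from 6.64 ± 0.536 to 2270 ± 113 CPM with Etv1 shRNA (8.42 ± 0.45, 1.02e-08). The chemokine receptor gene Ackr3 was at 0 counts with IL-4 under either hairpin and at least 217-fold and at least 127-fold higher with PGE2. Myb was at least 104-fold higher with control shRNA. Tlr5 rose by 8.47 ± 0.17 and 5.12 ± 0.13, Ramp3 by 9.40 ± 0.37 and 7.61 ± 0.38, and Got1 by 1.62 ± 0.09 and 1.28 ± 0.09 (control shRNA first). The endothelin gene Edn1 (-4.88 ± 0.40 and -5.14 ± 0.68), Batf3 (-4.77 ± 0.25 and -3.90 ± 0.37) and Nes (-3.76 ± 0.55 and -4.43 ± 0.83) fell under both. Ptgs2, the inducible cyclooxygenase, was at 26.1 ± 5.1 and 121 ± 63.5 CPM with control shRNA (2.20 ± 0.33, adjusted p = 7.44e-05) and at 17.6 ± 3.92 and 36.9 ± 9.27 CPM with Etv1 shRNA (1.06 ± 0.36, 0.0266). The latter call was lost with a replicate block nested in the hairpin (1.058, adjusted p = 0.0665). PGE2 changed 7360 genes with control shRNA (3630 higher, 3730 lower) and 5878 with Etv1 shRNA (3051 higher, 2827 lower). Between wild type and control shRNA cells 5210 called genes went the same way and 199 the opposite way.

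Cyclic AMP targets rose with PGE2 in both kinds of transduced cells. With control shRNA, 19 rose and 4 fell of 24 (camera adjusted p = 1.07e-06, and adjusted p = 0.116 with an estimated correlation). With Etv1 shRNA, 15 rose and 5 fell of 24 (camera adjusted p = 0.00118, and adjusted p = 0.274 with an estimated correlation). Crem rose by 5.20 ± 0.11 and 4.32 ± 0.11. HIF targets rose likewise. There 13 rose and 3 fell of 18 with control shRNA (camera adjusted p = 0.000915, and adjusted p = 0.0516 with an estimated correlation), and 12 rose and 3 fell of 18 with Etv1 shRNA (camera adjusted p = 0.00578, and adjusted p = 0.124 with an estimated correlation). Among them were Mxi1 (4.00 ± 0.13 and 3.19 ± 0.13) and the angiogenic factor Vegfa (4.29 ± 0.20 and 2.39 ± 0.19). Cholesterol synthesis genes rose, 13 rose and 2 fell of 23 (camera adjusted p = 0.0149, and adjusted p = 0.479 with an estimated correlation) with control shRNA. With Etv1 shRNA they did too, 16 rose and 1 fell of 23 (camera adjusted p = 0.00562, and adjusted p = 0.432 with an estimated correlation), for example Msmo1 (1.57 ± 0.08 and 1.14 ± 0.08). Cell cycle genes fell, 2 rose and 25 fell of 35 (camera adjusted p = 8.35e-06, and adjusted p = 0.116 with an estimated correlation) and 1 rose and 15 fell of 35 (camera adjusted p = 0.00592, and adjusted p = 0.325 with an estimated correlation). TCA cycle genes fell as a list with control shRNA (0 rose and 12 fell of 22; camera adjusted p = 0.0104, and adjusted p = 0.195 with an estimated correlation) and with Etv1 shRNA (2 rose and 12 fell of 22; camera adjusted p = 0.0194, and adjusted p = 0.274 with an estimated correlation). Fatty acid oxidation genes fell with control shRNA (2 rose and 12 fell of 19; camera adjusted p = 0.0206, and adjusted p = 0.322 with an estimated correlation). With Etv1 shRNA that list did not pass, with 2 rose and 8 fell of 19 (camera adjusted p = 0.357). Nor did the nuclear OXPHOS list under either hairpin, 8 rose and 22 fell of 76 and 10 rose and 12 fell of 76 (camera adjusted p = 0.302 and 0.998).

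Etv1 shRNA was compared with control shRNA in each condition to show what the knockdown changes. The ubiquitin ligase gene Nedd4 (ENSMUSG00000032216, chromosome 9, 72662346 to 72749852) was the most raised in unstimulated cells, from 0.322 to 61.2 CPM (7.59 ± 0.47, edgeR adjusted p = 1.38e-08, n = 3 per group), and was also higher under IL-4 (6.24 ± 0.43) and IL-4 with PGE2 (5.94 ± 0.42). The matrix protease gene Mmp9 (4.33 ± 0.76, 6.11 ± 1.02 and 5.34 ± 0.94) was higher in the same 3 conditions, as was the cortactin gene Cttn in unstimulated cells (4.53 ± 0.28) and under IL-4 (4.50 ± 0.30). The surface receptor gene Slamf7 was lower throughout (-4.56 ± 0.29, -4.43 ± 0.28 and -4.26 ± 0.30). Cx3cr1 (-4.46 ± 0.21; 11.5 ± 4.43 against 256 ± 42.1 CPM), Gdf15 (-4.06 ± 0.20), Npy (-4.00 ± 0.46) and Ccl4 (-3.71 ± 0.32) were lower in unstimulated cells. The receptor genes Csf3r (-3.50 ± 0.26 and -4.22 ± 0.33) and Cd300lf (-3.37 ± 0.30 and -4.29 ± 0.29) were lower under IL-4 and IL-4 with PGE2. Retnla was higher with Etv1 shRNA under IL-4 (3.84 ± 0.34; 75 ± 24.2 against 5.18 ± 1.4 CPM) and under IL-4 with PGE2 (3.86 ± 0.41). Among ETS family genes, Ets1 (-2.30 ± 0.23, -2.22 ± 0.21 and -2.74 ± 0.17) and Fli1 (-1.20 ± 0.07, -0.91 ± 0.07 and -1.06 ± 0.07) fell beside Etv1. The hairpins differed at 6405 genes in unstimulated cells (3084 higher with Etv1 shRNA, 3321 lower), at 6317 under IL-4 (3145 higher, 3172 lower) and at 6722 under IL-4 with PGE2 (3415 higher, 3307 lower). Of the calls in unstimulated cells and under IL-4 with PGE2, 4263 went the same way and 286 the opposite way.

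Of macrophage identity genes, 1 rose and 14 fell of 16 in unstimulated Etv1 shRNA cells, 1 rose and 13 fell of 16 under IL-4 and 1 rose and 11 fell of 16 under IL-4 with PGE2. Lyz2, the lysozyme gene of macrophages, was at -1.62 ± 0.07, -1.42 ± 0.07 and -1.47 ± 0.07, and the Fc receptor gene Fcgr3 at -1.46 ± 0.07, -1.82 ± 0.07 and -1.86 ± 0.07. Adgre1, which encodes F4/80 and was chosen after its values were seen, was the risen member, at 1 ± 0.21, 0.79 ± 0.21 and 0.91 ± 0.21. Camera gave adjusted p = 3.77e-05, 0.000111 and 7.35e-05, and adjusted p = 0.088, 0.146 and 0.121 with an estimated correlation. Inflammatory mediators were lower, 0 rose and 13 fell of 18, 1 rose and 13 fell of 18 and 0 rose and 18 fell of 18 in the same order, with Tnfaip3 at -2.33, -1.63 and -1.97 and Tnf at -1.90, -1.29 and -1.82. The inflammatory list had camera adjusted p = 4.01e-05, 0.000244 and 2.4e-07, and adjusted p = 0.088, 0.146 and 0.0383 with an estimated correlation. Cholesterol synthesis genes were higher, 13 rose and 0 fell of 23, 15 rose and 1 fell of 23 and 19 rose and 0 fell of 23. The cholesterol list had camera adjusted p = 4.01e-05, 3.39e-05 and 1.52e-05, and adjusted p = 0.365, 0.436 and 0.215 with an estimated correlation. Cell cycle genes were lower in unstimulated cells (3 rose and 22 fell of 35; camera adjusted p = 3.77e-05, and adjusted p = 0.16 with an estimated correlation) and under IL-4 (4 rose and 14 fell of 35; camera adjusted p = 0.0172, and adjusted p = 0.53 with an estimated correlation). Under IL-4 with PGE2, 11 rose and 6 fell of 35 (camera adjusted p = 0.488). Under IL-4 with PGE2 the cyclic AMP targets were lower (3 rose and 17 fell of 24; Crem -1.15 ± 0.08, Pde4b -1.71 ± 0.07; camera adjusted p = 0.000271, and adjusted p = 0.175 with an estimated correlation). Alternative activation genes were lower under IL-4 (3 rose and 17 fell of 28; camera adjusted p = 0.0105, and adjusted p = 0.597 with an estimated correlation). They were lower under IL-4 with PGE2 too (3 rose and 19 fell of 28; Tgm2 -1.44 ± 0.09; camera adjusted p = 0.000475, and adjusted p = 0.27 with an estimated correlation). TCA cycle genes were higher in all 3 conditions, 11 rose and 3 fell of 22, 11 rose and 2 fell of 22 and 13 rose and 1 fell of 22. The TCA cycle genes had camera adjusted p = 0.035, 0.0172 and 0.000475, and adjusted p = 0.365, 0.436 and 0.121 with an estimated correlation. Further lists that passed in a single condition were lysosome under IL-4, lower (6 rose and 17 fell of 25; camera adjusted p = 0.0223, and adjusted p = 0.663 with an estimated correlation), and a pair under IL-4 with PGE2. These were fatty acid oxidation, higher (12 rose and 2 fell of 19; camera adjusted p = 0.00214, and adjusted p = 0.175 with an estimated correlation), and HIF targets, lower (2 rose and 11 fell of 18; camera adjusted p = 0.0401, and adjusted p = 0.175 with an estimated correlation). The interferon list was lower in Etv1 shRNA cells in the 3 conditions, 0 rose and 5 fell of 27, 0 rose and 8 fell of 27 and 0 rose and 7 fell of 27. These counts were smaller when adjusted over the list alone: 0 rose and 2 fell, 0 rose and 3 fell and 0 rose and 4 fell. The list had camera adjusted p = 0.0159, 0.014 and 0.00725, and adjusted p = 0.806, 0.797 and 0.692 with an estimated correlation. In unstimulated control shRNA libraries its summed level was 3040, 7340 and 3690 CPM in replicates 1, 2 and 3. In Etv1 shRNA libraries it was 1740, 2560 and 3520 CPM. Under IL-4 the levels were 3020, 5760 and 2580 against 1550, 1810 and 3040 CPM, so the hairpins overlapped in both conditions. Under IL-4 with PGE2 they were 2930, 3560 and 2760 against 1560, 1410 and 1880 CPM, without overlap. Of all genes tested, 51.7%, 51% and 54.3% were called in the 3 conditions. Without the 3 control shRNA libraries numbered 2, 6522 genes differed in unstimulated cells. The interferon list was not tested again without them.

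The last comparisons asked whether Etv1 knockdown alters the response to PGE2, by testing the difference of the PGE2 effects between hairpins. Of 12382 genes, 1438 differed by edgeR, with 747 higher and 691 lower in Etv1 shRNA cells. Large differences downward included the phosphatase gene Dusp5 (-2.93 ± 0.12, adjusted p = 8.02e-12), with 296 counts in its lowest group. Tlr5 (-3.36 ± 0.33, 2.78e-06), the chemokine gene Ccl24 (-3.06 ± 0.64, 0.00324) and the protease inhibitor Timp1 (-2.81 ± 0.60, 0.00474) rested on 11, 15 and 19 counts there. Upward, Ptchd1 (2.00 ± 0.41), Etl4 (1.95 ± 0.53), Plscr4 (1.87 ± 0.26) and Serpinb6b (1.79 ± 0.11) had 60, 28, 77 and 974 counts in their lowest group. Of cyclic AMP targets, 2 differed upward and 15 downward of 24 (adjusted over the list alone, 2 and 18), with Crem at -0.88 ± 0.15 and Sik1 at -1.24 ± 0.15 (camera adjusted p = 1.06e-09, and adjusted p = 0.0423 with an estimated correlation). Of HIF targets, 1 and 7 of 18 differed (adjusted over the list alone, 1 and 8), with Vegfa at -1.90 ± 0.27 (camera adjusted p = 0.00123, and adjusted p = 0.0423 with an estimated correlation). Of cell cycle genes, 14 and 0 of 35 differed, with Ccnb1 at 1.22 ± 0.16 (camera adjusted p = 1.02e-05, and adjusted p = 0.121 with an estimated correlation). Most cyclic AMP and HIF targets rose with PGE2 under both hairpins, and many cell cycle genes fell. Over the PGE2 genes of wild type, the Etv1 shRNA effect had a slope of 0.691 on the control shRNA effect. Such a smaller effect in general would move these 3 lists the same way. Camera therefore does not tie the difference to these lists in particular. Further lists that passed were glycolysis (3 upward and 7 downward of 23; camera adjusted p = 0.00588, and adjusted p = 0.48 with an estimated correlation), inflammatory mediators (0 upward and 2 downward of 18; camera adjusted p = 0.00222, and adjusted p = 0.175 with an estimated correlation) and fatty acid oxidation (5 upward and 1 downward of 19, and 8 and 1 adjusted over the list alone; camera adjusted p = 0.00207, and adjusted p = 0.205 with an estimated correlation). The PGE2 effect of Got1 differed by -0.34 ± 0.12 (adjusted p = 0.0791) and that of Arg1 by -0.02 ± 0.28 (0.983). The replicate numbers paired the libraries within each hairpin, and a block of the number nested in the hairpin, chosen after seeing the data, gave 2563 genes (1376 higher, 1187 lower).

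Genes that PGE2 and valinomycin both moved in wild type were followed as a pair of sets. The 1019 raised genes had a median PGE2 effect of 0.415 with control shRNA and 0.316 with Etv1 shRNA, with a median difference of -0.114, 26 genes higher (44 with the replicate number as a block) and 167 lower (camera p = 2.1e-09, and p = 0.0255 with an estimated correlation). The 1018 lowered genes had medians of -0.474 and -0.334, with a median difference of 0.124, 135 genes higher (204 with the block) and 16 lower (camera p = 1.12e-07, and p = 0.0604 with an estimated correlation). Over all 7348 genes called for PGE2 in wild type, the Etv1 shRNA effect had a slope of 0.691 on the control shRNA effect. Signed by the wild type effect, the median difference was -0.119 for the shared genes and -0.113 for 4084 other PGE2 genes. Camera compared each set with all other genes, so a smaller PGE2 effect in general would also shift both sets. Its p-values therefore do not tie the shift to the sharing with valinomycin. The test of the difference for the IL-4 effect called 559 genes (335 higher, 224 lower), 984 (585 higher, 399 lower) with the replicate number as a block, and 361 and 360 without control shRNA IL-4 replicate 1 or 3. It called 1413 with the block nested in the hairpin and 1100 without the control shRNA libraries numbered 2, both chosen after seeing the data. Arg1 (-3.87 ± 0.73, adjusted p = 0.00843), the transcription factor Egr2 (-2.32 ± 0.36, 0.00242) and Socs1 (-2.27 ± 0.42, 0.00587) rose less with IL-4 in Etv1 shRNA cells. Jag1 (1.70 ± 0.14, 1.13e-06) and Cx3cr1 (2.45 ± 0.39, 0.00244) fell less. Arg1 rested on 14 counts in its lowest group. Unstimulated, it stood at 0.307 ± 0.0952 CPM with control and 1.77 ± 0.9 CPM with Etv1 shRNA. With IL-4 it stood at 596 ± 89.9 and 224 ± 51.2 CPM, so part of its difference lies in the unstimulated level. Cx3cr1 was likewise already lower in unstimulated Etv1 shRNA cells. Of the lists, alternative activation (0 upward and 5 downward of 28, and 0 and 8 adjusted over the list alone; camera adjusted p = 9.5e-10, and adjusted p = 0.121 with an estimated correlation) and cell cycle (6 upward and 0 downward of 35, and 10 and 0 adjusted over the list alone; camera adjusted p = 1.13e-05, and adjusted p = 0.123 with an estimated correlation) passed for the IL-4 difference. So did glycolysis (5 upward and 2 downward of 23, and 9 and 2 adjusted over the list alone; camera adjusted p = 0.000952, and adjusted p = 0.51 with an estimated correlation) and HIF targets (4 upward and 0 downward of 18; camera adjusted p = 0.000856, and adjusted p = 0.0501 with an estimated correlation). Of these HIF targets, Vegfa lost its call with the replicate number as a block (1.088, edgeR adjusted p = 0.0521).

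**Figure D5:**
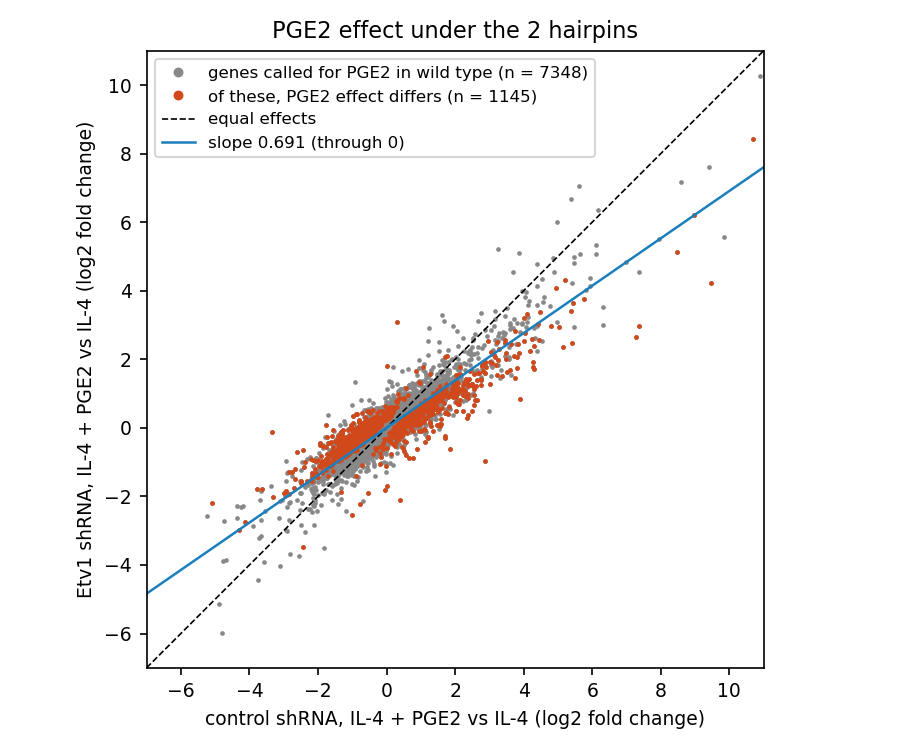
Log2 fold change of IL-4 with PGE2 against IL-4 in Etv1 shRNA cells against that in control shRNA cells, 1 point per gene for 7348 genes called for PGE2 in wild type; orange points differed by the interaction test. The solid line has the fitted slope of 0.691 through 0 and the dashed line marks equal effects.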

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

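The genes and summaries here were singled out because the PGE2 or IL-4 effect differed between Etv1 shRNA and control shRNA cells by the edgeR test of that difference. Of the tests in this part, the slope of the IL-4 effects, the 4 tests of the broad hairpin difference, the splits that keep pairs whole and every other setting that leaves out the control shRNA libraries numbered 2 or nests the block in the hairpin were chosen only after the result was seen; the matched draws and the PGE2 slope without the libraries numbered 2 were chosen before.

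The PGE2 effect differed at 1438 genes. Among cyclic AMP targets the differences were -0.88 for Crem, -1.24 for Sik1, -0.9 for Per1, -2.58 for the nuclear receptor gene Nr4a3 and, upward, 1.11 for Atf3. Among HIF targets they were -1.9 for Vegfa, -1.46 for Ndrg1, -0.81 for Mxi1 and -0.68 for Ero1l. Among cell cycle genes they were 1.22 for Ccnb1, 1.36 for Ccnb2, 1.5 for Cenpf and 0.61 for Mcm6. The other large negative differences were -4.64 for Tnfrsf9, -4.38 for Nrg1, -3.36 for Tlr5, -3.06 for Ccl24, -2.93 for Dusp5, -2.81 for Timp1 and -2.76 for Ptprf. The large positive ones were 3.26 for Fam174b, 2.9 for Map2, 2 for Ptchd1, 1.95 for Etl4, 1.87 for Plscr4, 1.84 for Lrrc39, 1.79 for Serpinb6b and 1.78 for Cdcp1. Dusp5 rose by 5.40 ± 0.10 with PGE2 in control shRNA cells and by 2.47 ± 0.08 in Etv1 shRNA cells. Fam174b, Map2, Tnfrsf9, Nrg1 and Ptprf had very few counts in 1 of the 4 groups, so their values depend on the prior count and are no bounds.

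The IL-4 effect differed at 559 genes. Of alternative activation genes, Arg1 differed by -3.87, Egr2 by -2.32, Socs1 by -2.27, Ptgs1 by -1.69 and Tgm2 by -0.68. The other large negative differences were -4.44 for Serpina3g, -2.1 for the amino acid oxidase gene Il4i1 (-2.053 with adjusted p = 0.0659, and no call, with the replicate number as a block), -1.93 for St7, -1.89 for Chst7 and -1.82 for Hebp2. Positive differences were 2.61 for Mycl, 2.45 for Cx3cr1, 2.27 for Sncaip, 2.09 for Nap1l2, 1.89 for Ccl4, 1.76 for Kcnk12, 1.7 for Jag1 and 1.55 for Atp2b4, and among cell cycle genes 0.68 for Tpx2, 0.65 for Kif11, 0.52 for Top2a and 0.5 for Mki67. Serpina3g and Mycl had very few counts in 1 group, and their values depend on the prior count.

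The first pattern is a smaller PGE2 effect in Etv1 shRNA cells: 69% of the 7348 PGE2 genes of wild type had a smaller effect there, the slope on the control shRNA effect was 0.691, and the genes shared with valinomycin had median differences of -0.114 (raised) and 0.124 (lowered). The tables argue against the control shRNA libraries numbered 2 as its source, since the slope without them was 0.683. Against wild type, the PGE2 slope was 1.062 for control and 0.777 for Etv1 shRNA, and the IL-4 slopes were 0.901 and 0.629. A smaller response of these cells to stimuli in general may account for the pattern, since the IL-4 effect had a slope of 0.693 on that of control shRNA cells. A change of the shared genes beyond other PGE2 genes stays open as a further part. Their median signed difference of -0.119 lay below 99.6% of 10000 draws matched on the size and direction of the wild type PGE2 effect (median -0.101, from -0.129 to -0.078). Without matching, the other PGE2 genes had a median of -0.113. The draws treat genes as independent, so that share does not measure the spread between libraries. Whether the smaller PGE2 effect follows from the lower Etv1 itself was not tested, because a single Etv1 hairpin group was analysed here.

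Other splits of the 12 libraries into hairpin groups within each stimulus bear on these differences. The 100 splits were drawn without regard to the replicate numbers, which pair the libraries of a hairpin, and the real split keeps all 6 pairs whole. For the number of genes with a different PGE2 effect, 7 of 100 splits gave as many as the real 1280 in a fit of these 4 groups alone, with 2092 as the highest other, so chance was not excluded. The raised set's median was matched or exceeded in size by 39 of 100 splits (highest other 0.3298) and the lowered set's by 11 of 100 (highest other 0.1595), so chance was not excluded for either set. For the IL-4 effect, 4 of 100 splits gave as many as the real 586 genes, with 718 as the highest other. That share is under 0.05, but among splits that ignore the pairs, so it is not taken to exclude chance. Its 559 genes in the fit of all groups became 361 and 360 without control shRNA IL-4 replicate 1 or 3. Splits that part pairs can exchange unequal numbers of libraries between the hairpins in the 2 stimuli. They then carry the broad hairpin difference into the result, a structure of the samples that raises the other splits. Only 10 splits keep the pairs whole, too few for a share under 0.05. Among these the real split gave 1280 genes for PGE2 and 586 for IL-4, with 0 as the highest other in each, and with each pair as a block 2348 and 1855, again with 0 as the highest other. The other such splits mix both hairpins in each group, so without the block the broad hairpin difference widens their spread. Their 0 was thus likely in advance and gives the real split no support. In the real split without the block, the sets had medians of 0.1134 (raised) and 0.1248 (lowered) in size. The highest others among the splits that keep pairs whole were 0.078 and 0.0964. With the block nested in the hairpin in the fit of all 18 libraries, 2563 genes differed for PGE2 and 1413 for IL-4.

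The second pattern is the broad difference between hairpins, of 6405, 6317 and 6722 genes in the 3 conditions, which the control shRNA libraries numbered 2 do not make, since 6522 genes were called in unstimulated cells without them. A lower share of macrophages in the Etv1 shRNA cultures as the whole cause would lower the 8 identity genes over 500 CPM by a common amount only if the replacing cells held none of their transcripts. These genes spread with a chi-square per degree of freedom of at least 31.8 in the 3 conditions, which argues against that form only. Among them were Adgre1 (1, 0.79 and 0.91), Tyrobp (-0.44, -0.31 and -0.28), Csf1r (-0.64, -0.61 and -0.71) and Lyz2 (-1.62, -1.42 and -1.47), chosen after their values were seen. Replacing cells that express these genes unequally could also give such a spread, and this was not tested. The chi-square rests on the spread between libraries, which may be technical. A lower share of macrophages as a part of the cause cannot be told apart, since of 17 markers of other cell types 5 were called higher, Ppbp, Pf4 and Gata2 among them, and 2 lower in unstimulated cells, most at few counts. Under IL-4 these were 7 higher and 3 lower, and under IL-4 with PGE2 4 and 3. Among markers with at least 5 CPM in the higher group, 2 were higher and 0 lower, 2 and 1, and 2 and 0 in the 3 conditions. Different cultures or transductions behind the hairpins cannot be told apart from the knockdown, since the labels do not say which cultures or transductions the libraries came from; the effect under IL-4 with PGE2 had a slope of 0.759 on that in unstimulated cells, as either would give. Off-target effects of the hairpin and loss of Etv1 stay open as untested explanations.

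For the comparisons of 3 libraries with 3, the 10 splits were too few for a share under 0.05, and 1 of 10, the real one, gave a result as large in each. The real splits, fitted on their 2 groups alone, gave 5897, 7377, 4340 and 7875 genes in wild type for IL-4, PGE2, valinomycin and PGE2 against valinomycin. They gave 3474 and 6413 for IL-4 and PGE2 with control shRNA, 2476 and 6120 with Etv1 shRNA, and 6008, 5825 and 6311 for the hairpin in unstimulated cells, under IL-4 and under IL-4 with PGE2. The highest of the other splits was 0 in each, but their groups mix the 2 conditions compared, which widens the spread, so 0 was likely in advance.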

How the results depend on the processing

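Every alternative that leaves out the control shRNA libraries numbered 2 or nests the replicate block in the hairpin was chosen after seeing the data. Most named genes kept their direction and their side of the threshold: under alternatives 20786 stayed, 234 passed anew, 708 were lost and 0 reversed. Of the list tests under alternatives, most of which had not passed as reported, 1218 stayed, 267 passed anew, 93 were lost and 2 reversed. Of the 93 losses, 84 came with the estimated correlation, under which only 8 of the 92 list passes held. Of those that passed anew, 105 came with the directional and 154 with the mixed fry test. The reversed ones were antigen presentation with PGE2 in wild type and in control shRNA cells, for which the directional fry test gave adjusted p values of 0.000195 and 0.0436 in the other direction. The cause was not tested, and the tests ask different questions. The fry values also depend on the order of groups in the model: with the order reversed, a check chosen after seeing the data, the control shRNA value was 0.0497. The difference of the PGE2 effects called 2563 genes with a replicate block nested in the hairpin. That of the IL-4 effects called 984 with the replicate block, 1413 with the nested block and 1100 without the libraries numbered 2; the cause was not tested. Requiring at least a 2-fold change in both left 43 shared genes for PGE2 and valinomycin, 72 for PGE2 in control shRNA and valinomycin, and 815 for PGE2 in wild type and control shRNA, by construction. The lowered set's difference was 0.124 with p = 0.0604 with an estimated correlation and 0.208 with p = 0.25 for the genes with at least 2-fold changes, a set of few genes. The raised set's difference became -0.848 for such genes (1 higher and 14 lower; camera with the preset correlation, p = 1.72e-09), against -0.114 as reported. There too a smaller PGE2 effect in general would shift the set. Etv1 under IL-4 in control shRNA cells (0.398 as reported) passed with the replicate block (0.391, adjusted p = 0.0156), with only the compared groups (0.399, 0.0384), with all 30 libraries (0.395, 0.0302), without the libraries numbered 2 (0.501, 0.0137) and with the nested block (0.392, 0.00954). In Etv1 shRNA cells it was lost with only the compared groups (0.677, adjusted p = 0.0564). For both, the value lay close to the threshold. With the replicate block, 36 calls of named genes were gained, that of Etv1 included, 3 were lost and 7 list tests passed anew. Lost were mt-Atp8 with IL-4 in wild type (-1.238, edgeR adjusted p = 0.0529), and Il4i1 and Vegfa in the difference of the IL-4 effects. The block moved the called members of the sets from 26 to 44 (raised set, higher) and from 135 to 204 (lowered set, higher). Among the counts of changed genes, shared calls, set tests and Etv1, the replicate block changed no other call and moved no other count by over 1.5 times. The nested block also ended the calls of Ptgs2 with PGE2 in Etv1 shRNA cells (1.058, edgeR adjusted p = 0.0665) and with IL-4 in control shRNA cells (1.275, adjusted p = 0.06). In the other comparisons not every same-numbered correlation was over 0.1. They ran from -0.074 to 0.015 for IL-4, 0.053 to 0.169 for PGE2, 0.075 to 0.123 for valinomycin and 0.089 to 0.198 for PGE2 against valinomycin in wild type, and from -0.023 to 0.251 between hairpins. Of the libraries, 17 of 18 shRNA and 9 of 12 wild type ones correlated best with their own number. These 9 were the wild type libraries given IL-4, alone or with an addition, so the numbers may pair those too.

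Leaving out 1 library at a time gave 5258 to 5825 genes for IL-4, 6987 to 7280 for PGE2, 4165 to 4687 for valinomycin and 7474 to 7828 for PGE2 against valinomycin in wild type. It gave 3490 to 4331 and 6543 to 7165 for IL-4 and PGE2 with control shRNA, and 1713 to 1822 and 5199 to 5297 with Etv1 shRNA. The hairpin contrasts gave 5670 to 6030 unstimulated, 5548 to 5981 under IL-4 and 5859 to 6547 under IL-4 with PGE2. The PGE2 difference gave 1107 to 1471 and the IL-4 difference 360 to 762, with 361 without control shRNA IL-4 replicate 1 and 360 without replicate 3. Shared calls ran from 1712 to 2107, 1644 to 1960 and 4823 to 5109, and the set medians from -0.14 to -0.093 and 0.11 to 0.149. Etv1 ran from 0.184 to 0.275, 1.094 to 1.179, -0.095 to 0.083 and 1.062 to 1.24 in the wild type contrasts, from 0.32 to 0.51 and 0.864 to 1.165 for IL-4 and PGE2 with control shRNA, and from 0.514 to 0.95 and 0.664 to 0.833 with Etv1 shRNA. Between hairpins it ran from -1.945 to -1.509, -1.506 to -1.327 and -1.815 to -1.514, and in the differences of effects from -0.42 to -0.12 and 0.116 to 0.552. The IL-4 call of Etv1 in control shRNA cells appeared without IL-4 replicate 2 (0.51, adjusted p = 0.027). That in Etv1 shRNA cells was lost without unstimulated replicate 2 (0.514, 0.208) or 3 (0.614, 0.157) and without IL-4 replicate 1 (0.607, 0.147), 2 (0.745, 0.0662) or 3 (0.737, 0.0692), with fewer libraries in each fit. Depth limits low genes most: in the shallowest library 3 counts correspond to 0.43 CPM.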

Other observations

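Both tests of mitochondrial ribosomal RNA in this part were chosen only after the result was seen. The hairpin contrasts held gene groups not described so far. Of the prostaglandin pathway list, 3 rose and 7 fell of 14 in unstimulated Etv1 shRNA cells, 5 rose and 5 fell of 14 under IL-4 and 3 rose and 5 fell of 14 under IL-4 with PGE2 (camera adjusted p = 0.276, 0.442 and 0.549). The prostacyclin receptor gene Ptgir was lower (-2.93 ± 0.16, -2.21 ± 0.12 and -2.68 ± 0.12), and so was Ptger2, which encodes the EP2 receptor for PGE2 (-2.17 ± 0.19, -1.45 ± 0.13 and -1.25 ± 0.14). Ptger4, which encodes the EP4 receptor, stood at -0.89 ± 0.11, 0.48 ± 0.12 and 0.19 ± 0.14 (adjusted p = 2.4e-06, 0.00265 and 0.266) and was chosen after its values were seen. The cytokine gene Il10 was higher with Etv1 shRNA in unstimulated cells (3.35 ± 0.27) and under IL-4 (3.41 ± 0.26). Ppbp, on the list of erythroid and megakaryocyte markers, was higher in all 3 conditions (3.53 ± 0.47, 2.63 ± 0.42 and 1.73 ± 0.20), and Gata2, on the mast cell and basophil list, in unstimulated cells (2.81 ± 0.34) and under IL-4 (1.16 ± 0.38). The glycolytic enzyme gene Gapdh was lower in each (-0.76 ± 0.06, -0.64 ± 0.06 and -0.68 ± 0.06).

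With valinomycin in wild type cells, 0 rose and 8 fell of 27 interferon response genes (camera adjusted p = 0.0326, and adjusted p = 0.467 with an estimated correlation), with Usp18 at -0.47 ± 0.09 and Ifit1 at -0.97 ± 0.29. Of macrophage identity genes, 2 rose and 8 fell of 16, with Fcgr1 at -0.65 ± 0.06 (camera adjusted p = 0.0165, and adjusted p = 0.4 with an estimated correlation). The glycolytic regulator Pfkfb3 (1.19 ± 0.07) and the sterol sensor partner Insig1 (1.29 ± 0.15) rose.

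The control shRNA libraries numbered 2 stood apart, at 12.94 to 21.87 chi-square per degree of freedom from the other replicates against 2.93 to 4.888 between numbers 1 and 3. Their interferon list summed to 7340, 5760 and 3560 CPM in unstimulated, IL-4 and IL-4 with PGE2 cells, against 2580 to 3690 CPM in the other 6 control shRNA libraries. Mrc1, the mannose receptor gene, chosen after its values were seen, was at 39, 814 and 1550 CPM in them, against 177 to 220, 1840 to 2080 and 3260 to 3660 CPM in the other control shRNA libraries of the same condition. The Etv1 shRNA libraries numbered 2 were also low in Mrc1, at 96, 726 and 837 CPM against 186 to 227, 1050 to 1100 and 1310 to 1340 CPM. Their interferon list was not raised, at 2560, 1810 and 1410 CPM, against up to 3520, 3040 and 1880 CPM in number 3. Between hairpins, the deviations of libraries numbered 2 correlated at 0.224, 0.17 and 0.251. Part of what sets number 2 apart may thus be shared by both hairpins.

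Mitochondrial ribosomal RNA took 0.751 to 0.846% of counts in the 3 valinomycin libraries and 0.017 to 0.0444% in the other 27 libraries. A rise of mitochondrial transcripts in general is argued against by the 8 tested protein genes of mitochondrial DNA, whose median log2 change was -0.357 (from -0.58 to 0.42, with 4 lower and 0 higher). Weaker selection of polyadenylated RNA in those libraries was tested with 15 nuclear RNAs of classes without a poly(A) tail, such as small nuclear and nucleolar RNAs. Their median change was -0.002 (quartiles -0.29 and 0.16, with 3 called higher and 0 lower), so they did not rise as a group. That does not settle the question, since many such RNAs are short and may be lost in library preparation. Longer RNAs without a tail were not examined. A change in the ribosomal RNAs themselves, such as their stability or polyadenylation under a low membrane potential, is a candidate explanation and was not tested. PGE2 libraries held mt-Rnr2 at 215 to 243 CPM, beside 111 to 214 CPM with IL-4 alone, and PGE2 against valinomycin gave -4.57 ± 0.23 by edgeR.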
